A study of Caenorhabditis elegans with 6 samples.

How the data were processed

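Gene expression was measured in whole Caenorhabditis elegans that had been raised to the fourth larval stage (L4) and then infected. Each sample had 1 Affymetrix array, hybridised with biotin-labelled cRNA made from 6 µg of total RNA. There were 3 arrays of wild-type animals and 3 of animals mutant for octr-1 (older name tag-24), and the titles call them biological replicates. Per the labels' protocols, eggs were released from gravid adults with bleach, kept for 22 hours in S basal medium, and the first-stage larvae were raised on Escherichia coli OP50 at 20 °C until L4. They then spent 4 hours at 25 °C with the pathogen Pseudomonas aeruginosa PA14 before RNA extraction, so both genotypes were infected and no uninfected arrays were analysed here.

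The deposited values are linear signal intensities, 1 per probe set and array, made with MAS5 per the submitters' processing notes. The MAS5 version and the settings are not given in the sources used here. The values bear a common scaling: after removal of the lowest and highest 2% of probe sets, the mean intensity was 500.1 on all 6 arrays, the mark of a target of 500. The authors' table holds no detection calls, so whether a probe set stood above background is unknown, and single-array MAS5 values are noisy at low intensity. The number of arrays limits the precision.

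Of the 22625 probe sets, 77 are Affymetrix controls and were kept out of all tests. Genes were named from the platform annotation: 20766 probe sets name 1 gene, 887 name several and 895 name none. The table of RefSeq genes for assembly WBcel235 matched 20701 of the 1-gene probe sets by Entrez number and changed 0 symbols. Probe sets naming several genes were tested but joined to no single gene. No coordinates are given, since no genome build is named for the array.

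Intensities were transformed to log2(value + 16) with no further normalization. Probe sets in the lowest 25% of the mean log2 level over all 6 arrays were left out, leaving 16911. The mutant was compared with wild type with limma 3.58.1 (lmFit, then eBayes with a trend of variance on mean level) in R 4.3.3, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. Because of the added 16, fold changes of dim probe sets are understated. Adjusted p-values of single genes are from this fit. Among 2510 genes with more than 1 tested probe set, 13 had probe sets called in opposite directions. For gene lists, each gene was represented by its 1-gene probe set with the highest mean level, giving 12920 genes.

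Before the data were examined, 33 gene lists were fixed (stress responses, immune effectors, cuticle and moulting, germ line, yolk, detoxification, fat metabolism, cell type markers, ribosome, proteasome and histones), and 5 written member names had no match. Lists were tested with camera at a preset inter-gene correlation of 0.01, against all other genes, with adjustment over the 33 lists. The same test with an estimated correlation, and fry, were run beside it. The rule for naming genes was also fixed then. It takes octr-1, the 10 genes with the largest change in each direction among called genes with no overlap between the groups, up to 4 genes with the smallest p of each list, and the tested abu probe sets. Other named members of a list were chosen after their values were seen.

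Replicate numbers are shared by the groups, but nothing in the labels says that a number marks a common day or culture. The numbers were therefore not used in the comparison, and a fit with them as a block was an alternative. Alternatives fixed in advance were quantile normalization, median centring, pseudocounts of 1 and 64, no filter, a filter on the lowest 50%, no variance trend, a replicate block, leaving out each array, a threshold of 0.10, an estimated correlation and the mean of a gene's probe sets. Centring on the hybridization controls was added after seeing the data. The fits were tested on simulated data with the real means, and with spreads averaged between each probe set and those of like level. For mutant against wild type over 16911 simulated probe sets, 100% of 50 raised by 2 on the log2 scale and 88% of 50 raised by 1 were recovered. The share was 54% of 50 lowered by 1 and 24% of 50 raised by 0.5, and 6 of 139 calls were false. Far fewer probe sets were changed there than were called in the data, so these rates do not carry over to it.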

Results

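The arrays compared animals labelled as mutant for octr-1, which encodes a neuronal receptor of the G protein-coupled family that binds octopamine, with wild type, both after 4 hours on the pathogenic bacterium P. aeruginosa PA14. The study is known for asking whether this receptor, acting in the nervous system, controls immune and unfolded protein response genes. There were 3 arrays per genotype. Median intensity was 109 ± 2.78 (SD, n = 3) in wild type and 148 ± 0.896 (SD, n = 3) in the mutant, although the trimmed means were equal. Arrays of 1 genotype correlated at 0.975 or more across probe sets, and arrays of different genotypes at 0.946 or less. The first principal component held 80.3% of the variance.

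The octr-1 probe set itself was lower in the mutant. Its signal was 142 ± 7.84 (SD, n = 3) in wild type and 59.6 ± 8.73 in the mutant, a log2 fold change of -1.07 ± 0.18 (SE; limma adjusted p = 6.5e-04). All 3 mutant arrays lay below all 3 wild-type arrays. The position of the probe set relative to the mutation is not given in the sources used here, so this value goes with the labels without testing the allele. Both enzymes that make octopamine were lower as well. Signal of tdc-1, the tyrosine decarboxylase, went from 823 ± 70.5 to 280.2 ± 58.9, and that of tbh-1, the tyramine beta-hydroxylase, from 1216 ± 344 to 309 ± 94.1 (log2 fold changes -1.52 and -1.92; limma adjusted p = 3.7e-05 and 8.0e-05). The RNA came from whole animals, so the cells in which these enzymes fell are not known. On the same arrays the oocyte and germ cell lists shifted by -1.67 and -0.51 relative to all genes. Of 20 pan-neuronal genes 13 rose and 3 fell as deposited, but 5 and 4 after median centring. The pan-neuronal list did not pass (camera adjusted p = 0.067). The list of octopamine and sensory neuron genes held 9 tested genes. Of these 3, octr-1 itself, tdc-1 and tbh-1, fell and 0 rose (3 adjusted over the list alone). The list was not tested without octr-1, the mutated gene. Its median shift relative to all genes was -0.45 (camera adjusted p = 0.032; adjusted p = 0.26 with an estimated correlation). The list no longer passed without wild-type replicate 2, wild-type replicate 3 or mutant replicate 2 (adjusted p = 0.078, 0.051 and 0.094), after median centring (0.086) or with no filter (0.20), and its adjusted p ranged from 0.011 to 0.26 over the alternatives.

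The difference between the genotypes reached across the array. Of 16911 probe sets tested, 4972 rose and 4018 fell in the mutant. With a change of over 2-fold, 1916 rose and 833 fell as deposited, 1386 and 1083 after quantile normalization, 997 and 2335 after median centring, and 1224 and 1752 after centring on the hybridization controls. With a pseudocount of 64 these were 1181 and 595. The groups did not overlap for 61.0% of probe sets, where chance gives 10%. The share of called probe sets that rose was 55.3% as deposited, 44.5% after quantile normalization, 26.9% after centring on the medians and 33.7% after centring on the hybridization controls. The median log2 fold change of the tested probe sets was 0.11, -0.07, -0.27 and -0.16 on those scales. Shifts of gene lists are therefore given below relative to the median of all genes. Control transcripts added at hybridization were 0.27 higher on the log2 scale in the mutant (10.51 ± 0.09 against 10.78 ± 0.12; exact permutation p = 0.10, the smallest that 3 against 3 allow).

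The 10 genes with the largest rises on the log2(value + 16) scale included 2 hedgehog-related genes and 2 cuticle collagens. One was grl-7, which encodes a hedgehog-related protein and went from 34.7 ± 25.6 to 2099 ± 197 (log2 fold change 5.49 ± 0.29 SE). Another was wrt-4, also hedgehog-related, from 70.9 ± 15.5 to 3777 ± 468 (5.45 ± 0.15). The others were gfi-1 (5.36), H23N18.5 (5.12), E01G4.6 (4.98), F15B9.8 (4.90), Y51H7C.13 (4.88), T17H7.7 (4.78), and the cuticle collagens col-71 (4.76) and bli-1 (4.69). Their limma adjusted p-values ran from 2.2e-09 for gfi-1 to 4.4e-07 for grl-7. The largest fall was that of bcf-1, from 6081 ± 309 to 45.8 ± 10.4 (log2 fold change -6.64 ± 0.14 SE; limma adjusted p = 3.1e-09). The other 9 falls were those of the collagens col-143 (-3.93) and col-101 (-3.82), the T-box gene sea-1 (-3.62), T04D3.5 (-3.51), R04D3.2 (-3.39), ztf-25 (-3.30), the innexin gap junction gene inx-3 (-3.24), C01G6.3 (-3.22) and R09F10.8 (-3.21), with adjusted p-values up to 3.1e-04. Against a signal near the floor the added 16 sets the size of a fold, so such genes have no order. The lower quartile of the arrays was at most 37.5, and mean signals near or under it were those of grl-7 and T17H7.7 in wild type and of bcf-1, sea-1 (9.11 ± 12.1), R04D3.2 (44.9 ± 54.6), ztf-25 (24.7 ± 15.5) and R09F10.8 (21.7 ± 31.6) in the mutant.

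Most genes of the moult and most cuticle collagens rose. Of 26 tested moulting genes, 21 rose, 2 fell and 3 did not pass, with the same 21 and 2 counts adjusted over the list alone. The median lay 1.97 above that of all genes (camera adjusted p = 5.2e-08; adjusted p = 0.14 with an estimated correlation). Signal of mlt-8 rose from 247 ± 3.33 to 2847 ± 376, that of noah-1, a component of the apical extracellular matrix, from 242 ± 45.3 to 2733 ± 348, and those of ptr-18 and cpz-1 by 3.38 and 1.93 on the log2 scale. The 2 that fell were nhr-23 (-0.61), a nuclear receptor that drives moulting, and the protease gene nas-37 (-0.45). Of 125 cuticle collagens, 83 rose and 18 fell (86 and 19 adjusted over the list alone), and the median lay 1.06 above that of all genes (camera adjusted p = 1.75e-11; adjusted p = 0.19 with an estimated correlation). Examples of rises were col-38, from 600.1 ± 60.3 to 12829 ± 562, rol-6, from 187 ± 8.73 to 4280.3 ± 416, and sqt-1, from 164 ± 19.7 to 3560 ± 259.8. The 18 that fell included col-143 (-3.93), col-101 (-3.82), col-8 (-2.63), col-142 (-2.21) and col-19 (-0.97), so the collagens did not move one way. Signal of col-8 fell from 6125 ± 1043 to 1055 ± 492.

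Hedgehog-related and patched-related genes behaved likewise, with 42 of 60 higher and 5 lower (42 and 5 adjusted over the list alone). Their median lay 1.29 above that of all genes (camera adjusted p = 2.8e-09; adjusted p = 0.14 with an estimated correlation). The 3 members that led by p after wrt-4 were grl-16 (3.99), wrt-6 (3.82) and ptr-18 (3.38). The 5 that fell were ptc-1 (-0.73), grd-10 (-1.25), grd-3 (-2.01), ptr-2 (-0.94) and grl-3 (-0.84). The hedgehog-related and moulting lists share 3 genes, ptr-18 among them. Genes of the pharyngeal gland and pharyngeal cuticle counted 17 higher and 3 lower of 32 (18 and 3 adjusted over the list alone), led by idpc-2 (1.73) and idpp-9 (2.48). Their median lay 0.58 above that of all genes (camera adjusted p = 0.015; adjusted p = 0.31 with an estimated correlation). That list did not pass after quantile normalization (adjusted p = 0.050) or with the lowest 50% of probe sets left out (0.17), with a range of 0.0018 to 0.31 over the alternatives.

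**Figure D1:**
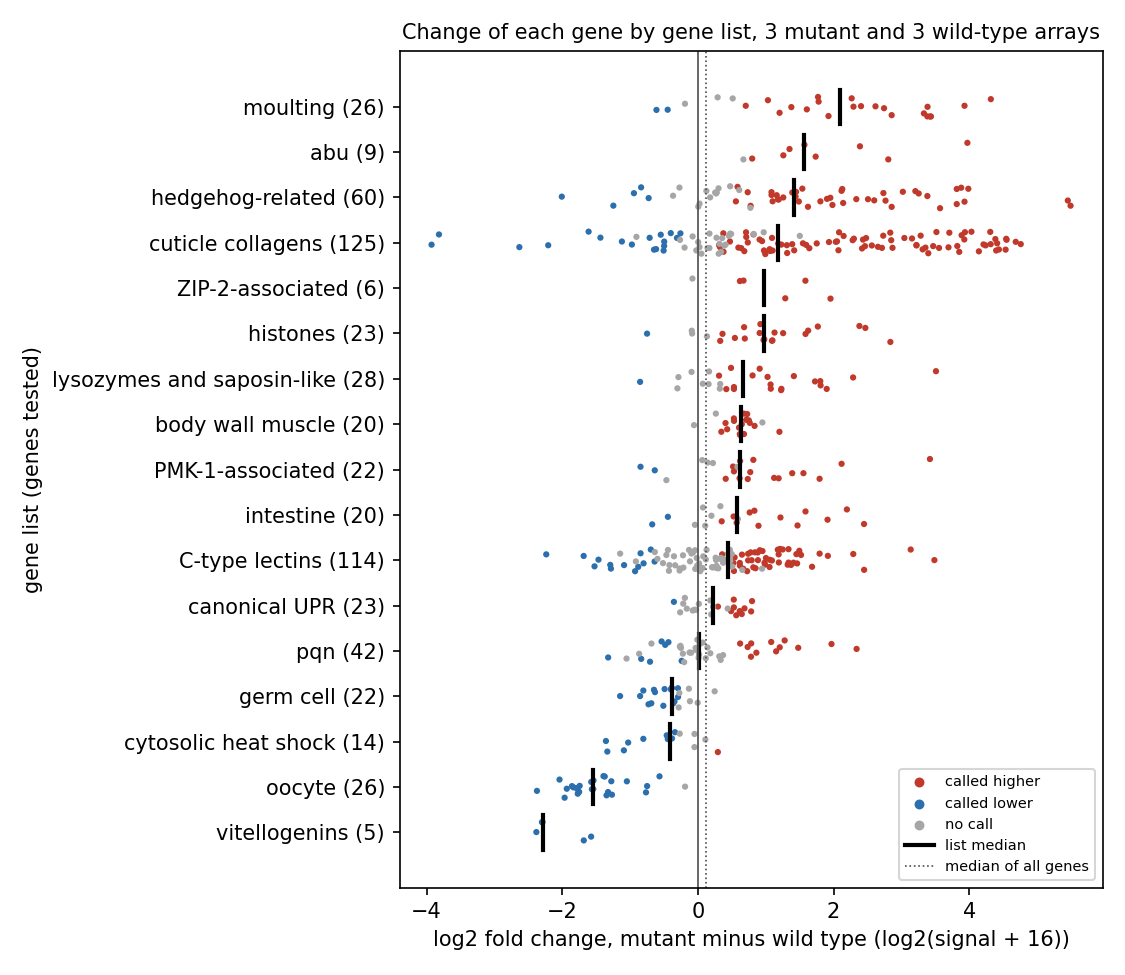
Each point is 1 gene, placed by its log2 fold change between mutant and wild-type arrays (x axis, log2(signal + 16) scale) within 17 gene lists (y axis, number of genes tested in brackets), and coloured by whether limma called it higher, lower or neither. Bars mark list medians, lowest at -2.29 for the vitellogenins and highest for the moulting genes, and the dotted line marks the median of all genes, 0.12; the medians of the pqn and canonical stress response lists, 0.01 and 0.22, turned to -0.37 and -0.16 after median centring.

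Genes of oocytes and yolk were lower in the mutant. Of 26 oocyte genes, 25 fell and 0 rose (26 adjusted over the list alone). The median shift relative to all genes was -1.67 (camera adjusted p = 2.9e-14; adjusted p = 0.26 with an estimated correlation). Signal of egg-2, an egg surface protein, fell from 4579 ± 382 to 1199 ± 236, that of mex-1 from 2775 ± 291 to 669 ± 131, that of pie-1, a maternal regulator of germ line fate, from 1896 ± 223 to 639 ± 62.2, and that of egg-3 from 1920.1 ± 91.1 to 569 ± 113. All 5 tested vitellogenins, which encode yolk proteins, fell (5 adjusted over the list alone), with a median shift of -2.41 relative to all genes (camera adjusted p = 0.0012; adjusted p = 0.27 with an estimated correlation). For vit-5 the signal fell from 13672 ± 1397 to 2783 ± 1260.1, and log2 fold changes of vit-4, vit-6 and vit-1 were -2.29, -1.68 and -2.30.

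Of 22 germ cell genes, 16 fell and 0 rose (17 adjusted over the list alone), with a median shift of -0.51 relative to all genes (camera adjusted p = 1.8e-05; adjusted p = 0.19 with an estimated correlation). They included spo-11 (-0.85), which makes the meiotic DNA breaks, deps-1 (-1.15), glh-2 (-0.81) and him-8 (-0.73). Of 74 sperm genes, 35 rose and 4 fell (35 and 4 adjusted over the list alone), among them spe-41 (1.01), spe-4 (1.11) and spe-21 (0.98), while spe-39 fell (-1.17). The sperm median lay 0.12 above that of all genes (camera adjusted p = 0.012; adjusted p = 0.62 with an estimated correlation). After median centring, 8 sperm genes rose and 20 fell, so no direction is given for that list. It did not pass under the 3 other scalings or without wild-type replicate 3 (adjusted p = 0.096), with a range of 0.0023 to 0.93 over the alternatives.

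The abu genes, named for their activation when the unfolded protein response is blocked, were higher. Of 9 genes with a tested probe set that names no other gene, 8 rose and 0 fell (8 adjusted over the list alone), and 7 rose under each of the other 3 scalings. The median lay 1.45 above that of all genes (camera adjusted p = 1.2e-04; adjusted p = 0.19 with an estimated correlation). The study is known to have singled these genes out on these arrays, so their count is not independent evidence of the direction. Signal of abu-13 rose from 92.2 ± 6.47 to 1684 ± 107, and that of abu-14 from 181 ± 22.9 to 1013 ± 101. Log2 fold changes were 2.81 for abu-12, 1.74 for abu-8, 1.57 for abu-15, 1.35 for abu-6, 1.26 for abu-11 and 0.80 for abu-4. The last was not called under the other 3 scalings. For abu-10 the value was 0.67 (limma adjusted p = 0.095), and without wild-type replicate 3 it was 0.92 (limma adjusted p = 0.036; range 0.036 to 0.46 over the alternatives). Over all 16 tested probe sets that name an abu gene, 14 rose and 0 fell, but 5 of them name several near-identical genes and their signal cannot be assigned. Among the others, only those of abu-10 and abu-14 lack the suffix that marks probes shared with other transcripts, so most may carry shared signal too. On the same arrays the shifts of the moulting and oocyte lists relative to all genes were 1.97 and -1.67.

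The wider pqn family, proteins rich in glutamine and asparagine, showed no shift as a list. Of 42 tested genes, 12 rose and 7 fell (12 and 7 adjusted over the list alone), with a median shift of -0.11 relative to all genes (camera adjusted p = 0.94). The leading members were pqn-89 (1.48), pqn-63 (1.97), pqn-13 (1.28) and pqn-21 (-0.84). The direction of its median flipped with the scaling, from 0.01 as deposited to -0.24 after quantile normalization. Among 23 genes of the canonical endoplasmic reticulum stress response, 10 rose and 1 fell (10 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.11). The chaperone gene hsp-3 rose from 4566 ± 111 to 7877 ± 161, and enpl-1 (0.62), crt-1 (0.56) and pdi-3 (0.49) were also called. The listed gene that fell was disl-2 (-0.35). It was entered by its locus name, F48E8.6, and whether it belongs to the stress response was not checked. After median centring 3 of these genes rose and 9 fell, and crt-1 and pdi-3 were no longer called there or after centring on the hybridization controls. The list passed after quantile normalization (adjusted p = 0.033; range 0.033 to 0.65 over the alternatives).

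Most genes in the lists for the immune regulators PMK-1 and ZIP-2 were higher. Of 22 genes used as readouts of the p38 kinase PMK-1, a regulator of intestinal defence, 15 rose and 2 fell (16 and 2 adjusted over the list alone). The median lay 0.50 above that of all genes (camera adjusted p = 6.4e-04; adjusted p = 0.26 with an estimated correlation). Signal of the C-type lectin clec-67 rose from 799 ± 47.8 to 2824 ± 387, and that of dod-22 from 928 ± 170 to 4089 ± 756, while K08D8.4 and F55G11.8 rose by 3.42 and 1.39 on the log2 scale. The 2 that fell were F01D5.5 (-0.85) and mul-1 (-0.64). Of 6 infection genes associated with the transcription factor ZIP-2, 5 rose, namely irg-2 (1.95), irg-1 (1.58), Y37A1A.2 (1.29), zip-2 itself (0.67) and oac-32 (0.62), and 0 fell (5 adjusted over the list alone). Their median lay 0.86 above that of all genes (camera adjusted p = 0.026; adjusted p = 0.26 with an estimated correlation). On the same arrays the median of 20 intestinal markers lay 0.46 above that of all genes and that of 26 moulting genes 1.97 above.

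Antimicrobial families followed in part, but the lists share members and are not separate evidence. As written, the C-type lectin and PMK-1 lists share 5 genes, clec-67 among them. The lysozyme list shares 1 gene with the PMK-1 list and 6 with the DAF-16 list. Of 28 lysozymes and saposin-like proteins, 19 rose and 1, spp-23 (-0.85), fell (19 and 1 adjusted over the list alone), with a median 0.55 above that of all genes (camera adjusted p = 1.7e-04; adjusted p = 0.26 with an estimated correlation). They were led by spp-13, from 60.2 ± 17.8 to 845 ± 169, and lys-4, from 1726 ± 311 to 6428 ± 554. Of 114 C-type lectins, 50 rose and 13 fell (50 and 13 adjusted over the list alone). The lectin median lay 0.33 above that of all genes (camera adjusted p = 0.018; adjusted p = 0.26 with an estimated correlation). That list did not pass after quantile normalization (adjusted p = 0.076), with no filter (0.15) or without mutant replicate 2 (0.061), with a range of 3.7e-06 to 0.26 over the alternatives. The leading lectins were clec-230 (3.14), clec-72 (2.29), clec-67 (1.79) and clec-91 (-2.24). Among 21 epidermal peptides, 8 rose and 4 fell (8 and 4 adjusted over the list alone). Among those that rose were cnc-4 (2.22), nlp-33 (1.98), nlp-30 (2.25) and cnc-3 (2.19). The list median was -0.08 while its mean, 0.43, and the direction of the test were higher, and the list did not pass (camera adjusted p = 0.51). Targets of DAF-16, the transcription factor of the insulin pathway, counted 11 higher and 4 lower of 23 (11 and 4 adjusted over the list alone), led by nnt-1 (2.52), spp-1 (1.41), mtl-2 (0.83) and mtl-1 (2.26), and did not pass as a list (camera adjusted p = 0.13). Their median was 0.35 as deposited and -0.038 after median centring.

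Most markers of the intestine and of body wall muscle were higher too. Of 20 intestinal markers, 12 rose and 2 fell (12 and 2 adjusted over the list alone), with a median 0.46 above that of all genes (camera adjusted p = 5.2e-04; adjusted p = 0.19 with an estimated correlation). The cathepsin B-like protease genes cpr-5, cpr-4 and cpr-1 were among the leading members, with log2 fold changes of 1.91, 2.45 and 1.59. The 2 that fell were pept-1 (-0.67) and elo-5 (-0.44). Of 20 body wall muscle markers, 17 rose and 0 fell (18 adjusted over the list alone), with a median 0.51 above that of all genes (camera adjusted p = 1.4e-05; adjusted p = 0.18 with an estimated correlation). The myosin heavy chain gene unc-54 rose from 5746 ± 440 to 9660.3 ± 179. Pan-neuronal genes counted 13 higher and 3 lower of 20 (13 and 3 adjusted over the list alone), led by unc-64 (0.69), mec-12 (1.10), egl-3 (0.85) and sbt-1 (0.75), and did not pass (camera adjusted p = 0.067). The 3 that fell were unc-31 (-1.30), ehs-1 (-0.54) and unc-119 (-0.47). After median centring 5 pan-neuronal genes rose and 4 fell, after centring on the hybridization controls 7 and 4, and after quantile normalization 9 and 3. The pan-neuronal list passed without wild-type replicate 3 (adjusted p = 0.023), with no filter (0.044) and with the lowest 50% left out (0.026), with a range of 0.023 to 0.48 over the alternatives, the highest with an estimated correlation.

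**Figure D2:**
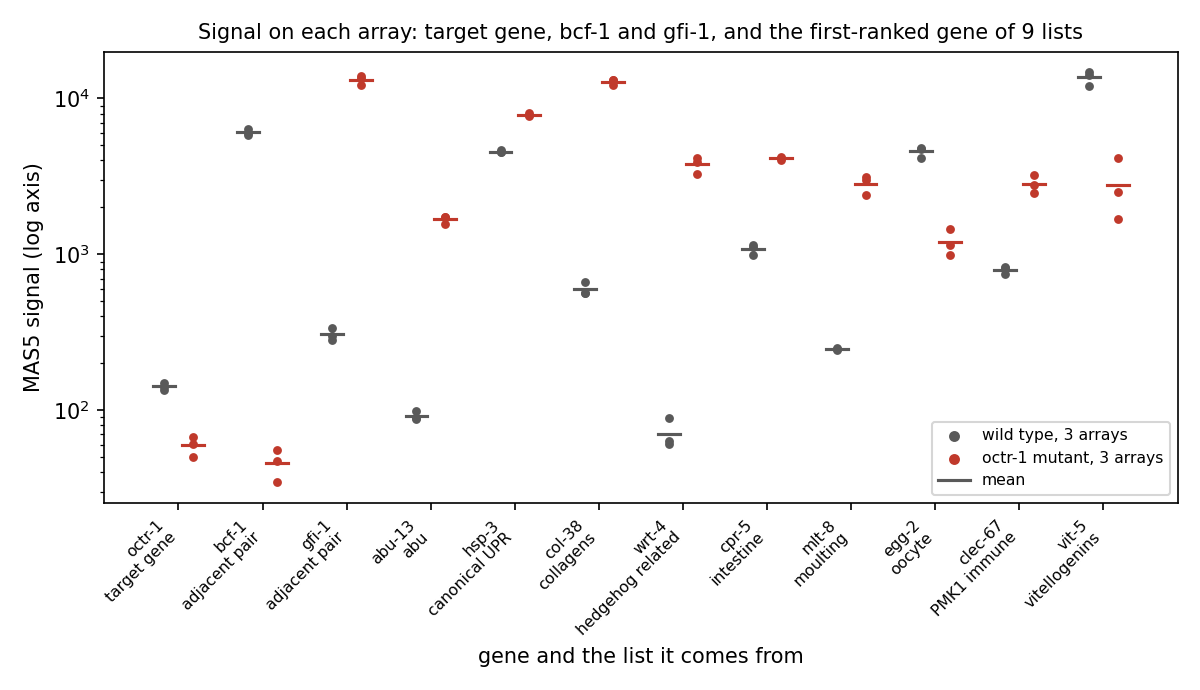
MAS5 signal on each of the 6 arrays (y axis, log scale) for octr-1, for bcf-1 and gfi-1, and for the gene with the smallest p in 9 of the gene lists (x axis); points are arrays and short lines are group means. The 3 arrays of each genotype do not overlap for any of the 12 genes, with octr-1 between 135 and 151 in wild type and between 50.4 and 67.7 in the mutant. Apart from octr-1 the genes were chosen by lack of overlap or by smallest p, so this follows largely from the choice. It also held for 61.0% of all tested probe sets.

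Counts of higher and lower genes shifted with the centring in other lists too. After median centring they were 9 and 5 for the intestine, 9 and 1 for body wall muscle, 11 and 3 for the PMK-1 readouts, 14 and 3 for the lysozymes, 33 and 22 for the C-type lectins, 7 and 8 for the epidermal peptides, 7 and 5 for the DAF-16 targets, 8 and 19 for the pqn genes and 0 and 6 for the octopamine and sensory genes.

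In total 23 of the 33 lists passed camera with the preset correlation, 16 higher and 7 lower on the values as deposited. The 16 include the sperm and ribosome lists, whose counts turned after median centring and which are given no direction. Over the same lists fry, which asks whether the genes of a list move one way, called 31. With an estimated correlation camera called 0, and 6 had an unadjusted p under 0.05. When the 6 arrays were regrouped into other sets of 3 and 3, the preset test called 12 to 20 lists. In those groupings limma called 0 probe sets, and 91 to 232 had an unadjusted p under 0.05. Each set there mixed both genotypes, so these are not the counts of arrays without a difference.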

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

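The control probe sets, which no comparison used, carried a difference between the genotypes and were looked at after the main result was seen. The mean log2 value of 18 hybridization control probe sets was 0.27 higher in the mutant (10.51 ± 0.09 against 10.78 ± 0.12, SD, n = 3), and all 18 were higher. The mean of 24 probe sets for the transcripts added before labelling was 0.41 higher (7.89 ± 0.07 against 8.29 ± 0.10, SD, n = 3), and all 24 were higher. The lowest median difference of the labelling controls over the 9 pairs of a mutant and a wild-type array was 0.26. A lower sample signal before the scaling to a common target is a possible explanation, but this value was looked at after both sets were seen to be higher and restates that, so it decides nothing. A different amount of control transcript added per sample was not tested, and either bears on the direction of the changes as deposited. The exact permutation p was 0.10 for both, the smallest that 3 against 3 arrays allow. The ratio of 3' to 5' signal overlapped between the genotypes. It was 1.59 ± 0.27 and 1.44 ± 0.18 for actin (exact permutation p = 0.50) and 1.39 ± 0.17 and 1.31 ± 0.10 for GAPDH (exact permutation p = 0.60). No group held the 4 arrays needed to look for a single outlying array.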

How the results depend on the processing

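The scaling of the arrays changed the counts most. Higher and lower probe sets numbered 4972 and 4018 as deposited, 3528 and 4407 after quantile normalization, 2515 and 6825 after median centring, and 2800 and 5512 after centring on the hybridization controls, a setting chosen after seeing the data. Each centring moves all genes by 1 amount per array, which shifts the split by construction. Over all other settings run (pseudocounts of 1 and 64, no filter, the lowest 50% left out, no variance trend, the replicate block, a threshold of 0.10) the counts stayed within 1.5 times the main ones. Leaving out each array in turn gave 4245 to 4880 higher and 3297 to 3792 lower. The replicate block gave 4939 and 4005 and changed no call of the lists or named genes. Deviations from the group means correlated at -0.04, 0.10 and 0.06 between arrays of the same number, not each over 0.1, so the numbers are not taken as pairs; 3 of the 6 arrays correlated best with their own number in the other group. The fall of octr-1 ranged from -1.15 to -0.98 without 1 array and was called each time. The shift of the abu list was 1.31 to 1.57 without 1 array and 1.45 with an estimated correlation, where it no longer passed (adjusted p = 0.19); that of the pqn list was -0.18 to -0.04 and never passed. Lists called numbered 23, 21 to 23 without 1 array, and 0 with an estimated correlation. Turned in sign, all without passing before or after, were the cytochrome P450 list (-0.024 after quantile normalization, -0.056 to 0.20 without 1 array, the lowest without mutant replicate 3), the epidermal peptide list (0.012) and the mitochondrial stress list (0.030) after quantile normalization, and the probe set shared by pqn-57 and abu-9 (-0.079 after quantile normalization, -0.083 after median centring). The cause was not tested. Genes that a filter left out had no value under it. Of the remaining list values under an alternative, 474 kept direction and side of the threshold, 43 lost the call and 4 gained it; for named genes these were 2326, 25 and 12. In the real grouping limma called 8990 probe sets, against 0 in each other grouping (91 to 232 at an unadjusted p under 0.05), and camera 23 lists against at most 20. The real grouping alone reached its count (1 of 10 groupings, for both), and 10 groupings are too few for a share under 0.05. Every other grouping mixes arrays of both genotypes, so the difference between genotypes adds to the spread within its sets. The 0 calls of probe sets there could be foreseen from that, and the counts there do not measure false calls.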

Other observations

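Of the tests given here, those on array scaling, germ cell number and the abu genes were chosen after the results they measure were seen, and those on embryonic genes, adult collagens and the neighbours of bcf-1 were written down before those values were seen, though after the genes with the largest changes had been. Of 23 histone genes, 19 rose and 1, his-74 (-0.75), fell (19 and 1 adjusted over the list alone), led by his-39 (2.47), his-4 (2.84), his-3 (1.77) and his-24 (2.38). Their median lay 0.85 above that of all genes (camera adjusted p = 1.0e-05; adjusted p = 0.26 with an estimated correlation), and many histone genes are near-identical copies whose signals cannot be separated. Of 33 proteasome subunits, 22 fell and 1, rpn-6.2 (0.38), rose (23 and 1 adjusted over the list alone), with a median shift of -0.37 relative to all genes (camera adjusted p = 3.9e-05; adjusted p = 0.19 with an estimated correlation). They included rpn-6.1 (-0.46), rpn-7 (-0.51), rpt-5 (-0.40) and rpn-9 (-0.43). Of 62 ribosomal protein genes, 59 rose and 0 fell as deposited (59 adjusted over the list alone; camera adjusted p = 7.8e-10; adjusted p = 0.26 with an estimated correlation), led by rpl-11.2 (0.78), but 2 rose and 1 fell after quantile normalization and 1 rose and 4 fell after median centring, so no direction is given. The ribosome list did not pass after quantile normalization (adjusted p = 0.93), median centring (0.97) or centring on the hybridization controls (0.055), with a range of 1.7e-10 to 0.97 over the alternatives. Cytosolic heat shock genes counted 9 lower and 1, hsp-25 (0.29), higher of 14 (9 and 1 adjusted over the list alone), led by hsp-43 (-1.09) and dnj-19 (-0.81). Their median shift relative to all genes was -0.53 (camera adjusted p = 0.0078; adjusted p = 0.26 with an estimated correlation). Of 17 apoptosis and engulfment genes 7 fell and 0 rose (7 adjusted over the list alone), among them crn-1 (-0.70), ced-6 (-0.79), ced-5 (-0.71) and ced-4 (-0.75). Their median shift relative to all genes was -0.55 (camera adjusted p = 0.0026; adjusted p = 0.19 with an estimated correlation).

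Of 63 neuropeptide and insulin-like genes, 32 rose and 4 fell (32 and 4 adjusted over the list alone), led by nlp-20 (2.28), nlp-17 (1.83), flp-5 (1.31) and nlp-1 (1.64). The 4 that fell were nlp-47 (-1.08), ins-34 (-1.71), ins-7 (-0.57) and ins-23 (-0.98), and the median lay 0.32 above that of all genes (camera adjusted p = 0.0013; adjusted p = 0.26 with an estimated correlation). Of 54 UDP-glucuronosyltransferases, 23 rose and 7 fell (23 and 7 adjusted over the list alone), led by ugt-50 (2.35) and ugt-6 (1.93), with a median 0.30 above that of all genes (camera adjusted p = 0.037; adjusted p = 0.19 with an estimated correlation). That list did not pass without wild-type replicate 2 (adjusted p = 0.060) or mutant replicate 1 (0.051), after quantile normalization (0.050) or without the variance trend (0.057), with a range of 0.0013 to 0.19 over the alternatives. Cytochrome P450 genes counted 21 higher and 9 lower of 54 (22 and 9 adjusted over the list alone), with cyp-37B1 at 3.26 and cyp-31A5 at -1.64, and glutathione transferases 6 higher and 9 lower of 30 (6 and 8 adjusted over the list alone), with gst-22 at 1.19 and gst-40 at -1.65. After median centring 2 glutathione transferases rose and 15 fell, and after centring on the hybridization controls 2 and 14. Neither list passed (camera adjusted p = 0.27 and 0.21), and the P450 median was 0.19 as deposited and -0.20 after median centring. Fat metabolism genes counted 11 higher and 6 lower of 30 (11 and 6 adjusted over the list alone; camera adjusted p = 0.61), and their median was 0.20 as deposited and -0.18 after median centring. Among them the desaturase gene fat-6 fell from 4201 ± 468 to 1435 ± 132 and fat-5, near the floor in the mutant, fell by 2.38 on the log2 scale, while cpt-4 (1.32) and lipl-2 (1.61) rose. Mitochondrial stress genes counted 1 higher, dve-1 (0.86), and 2 lower, hsp-60 (-0.55) and lonp-1 (-0.39, not called after quantile normalization), of 7 (1 and 2 adjusted over the list alone; camera adjusted p = 0.32). Pharyngeal muscle markers counted 1 higher, pha-4 (1.37), and 2 lower, tni-4 (-1.05) and tnc-2 (-0.45), of 8 (1 and 1 adjusted over the list alone; camera adjusted p = 0.37), and tnc-2 was not called in 7 of 15 alternatives, 5 of them leaving out 1 array (all except wild-type replicate 2; limma adjusted p from 0.0019 to 0.15 over the alternatives). After median centring the higher and lower counts were 15 and 12 for the UDP-glucuronosyltransferases, 11 and 14 for the P450 genes, 19 and 6 for the neuropeptides, 5 and 11 for fat metabolism, 1 and 6 for the mitochondrial stress genes, 1 and 5 for pharyngeal muscle, 0 and 32 for the proteasome, and 0 and 13 for both the heat shock and the apoptosis genes.

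The joint rise of moulting and cuticle genes and fall of oocyte and yolk genes is the pattern that holds the highest and the lowest list median. Uneven scaling along the range of intensity argues poorly for it, since the gap between the moulting and oocyte medians was 3.65 on the log2 scale as deposited and 3.50 after quantile normalization, while centring cannot change a gap between lists. Fewer germ cells per animal, as the whole cause, would raise somatic markers alike, but the moulting median exceeded that of body wall muscle by 1.46 (permutation p over genes = 8.2e-04). That p treats genes as replicates and says nothing of the spread between animals, and both medians were known when the test was chosen. The values show only that these lists did not rise alike on these arrays. A candidate explanation is that the mutant animals were younger on average at harvest, before the adult moult and oocyte production. Early zygotic genes, chosen as a sign of embryos in the sample, had a median of -0.11 relative to all genes. Of matched random lists, 8.46% fell at or below that value. Of 42 such genes 20 were tested, with 6 lower and 5 higher. The largest falls were those of vet-2 (-2.31, near the floor in the mutant), tbx-9 (-2.07), nhr-2 (-1.57) and pal-1 (-1.55). The largest called rises were those of nob-1 (1.06), sdz-24 (0.98) and hlh-1 (0.84). The last is also in the body wall muscle list, of which 17 of 20 rose, so these genes do not measure embryos alone. RNA was taken after 4 hours of infection begun at L4, and whether either genotype carried embryos by then is not known. Several members lay near the floor in wild type (hlh-1 at 23.5, end-1 at 27.1 and ceh-27 at 28.4). For both reasons the early zygotic list cannot tell younger from older animals here. Of 2 tested adult collagens 1, col-19 (-0.97), was lower and col-129 (-0.02) did not pass. The early zygotic and adult collagen values do not decide age, which stays open. The design holds no arrays that would part slower growth of the mutant from an earlier harvest. Nor does it part either from an effect of the receptor on the moulting, cuticle, oocyte and yolk genes.

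The rise of the abu genes may belong to the same pattern. Their median lay at the 61.1st percentile of draws of 9 genes from the 208 moulting, collagen and hedgehog-related genes, but 95% of draws spanned 0.27 to 3.22, a range that also held 11 of the 12 other lists called higher, so the test decides nothing and an effect of genotype on these genes stays open. Signal shared between near-identical copies stays open: both probe sets of abu-14 without the suffix that marks shared probes (2 of 2) were called higher, but the suffix alone does not exclude cross-hybridization, and probe sequences were not used here. For the abu genes other than abu-10 and abu-14, 0 probe sets without such a suffix were tested.

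The largest fall among the tested probe sets, that of bcf-1, and the rise of gfi-1 belong to neighbouring genes (F57F4.4 and F57F4.3). Among 12494 pairs of adjacent tested genes this was the only pair with opposite changes of over 3 on the log2 scale, and 0 others were found. The pair was noticed for the size of its changes, and only 143 of 16911 probe sets were called lower by over 4-fold. Few other such pairs could thus be found, so being the only one says little. Both values come from probe sets whose suffix marks probes that can be shared with other transcripts, and whether they can pick up each other's transcript was not checked. A large deletion or duplication around the pair would take neighbours with it. All 4 flanking genes (F13H6.5, F57F4.1, cht-6 and urb-1) changed by under 1 relative to all genes, from -0.33 to 0.47. A doubling of copies would itself add at most 1, so that bound does not exclude a duplication. Beside bcf-1, cht-6 had a wild-type signal of 58.0 ± 14.1, near the 45.8 of bcf-1 in the mutant. Its loss could therefore hardly show. Farther out, urb-1 went from 1349 ± 183 to 1165 ± 158, which argues against a complete loss reaching that gene. A difference between the strains confined to the pair is a possible explanation that was not tested, and so is an effect of the receptor on these genes.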
